A study of Mus musculus with 6 samples.

How the data were processed

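Gene expression was measured by bulk RNA sequencing in 6 mouse livers, 3 from control animals and 3 from animals given inosine by intraperitoneal injection. Inosine is the purine nucleoside that forms when adenosine is deaminated. Total RNA was extracted with Trizol, per the labels' protocols. The design text speaks of mice that received the injection. It does not say in so many words that each library came from its own animal, so the p-values measure the spread between these libraries. Sex, strain, dose, number of injections and time of tissue collection are not given in the sources used here.

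One table of the whole series was used. The authors deposited estimated read counts per gene that need not be whole numbers, which is the form in which RSEM writes expected counts. Bowtie2, RSEM and the genome build GRCm39 are named, without versions, per the submitters' processing notes. Whether the libraries kept strand information is not given in the sources used here. The authors deposited FPKM and TPM values for each library beside the counts; these served for checks of the columns, and FPKM together with the counts gave each gene's effective length. The authors also deposited a log2 fold change of inosine over control with a p-value and a q-value from DESeq2 for each gene, per the file headers. These came from their own comparison and are named as such wherever they are printed. The table held 16375 genes, all typed as mRNA, and 1 line without content, which was left out. Mitochondrially encoded genes were not analysed here, so no share of mitochondrial reads is given. All 18 columns of per-sample values matched the title of a single library, and 0 were left unmapped.

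Between 89.8% and 90.3% of the deposited counts in a library were exactly whole. They were rounded to whole numbers before any count test. Totals ran from 16383896 to 17505035 counts per library. A count of 0 allows up to 3 counts, or 0.171 to 0.183 CPM (counts scaled by the total of the library) depending on the library. These floors cover counting error alone. The counts hold no molecular identifiers that are used here, so copies made by PCR are not told apart. No 2 libraries of a group agreed within sampling noise. The chi-square statistic per gene ran from 27.3 to 115.1 over the pairs within a group, so none was treated as a second deposit of another. This does not show that the libraries came from separate animals.

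The main comparison used the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest at their defaults) in R 4.3.3, with all 6 libraries, TMM scaling and the group as the only term. The default low-count filter of edgeR, built on a count of 10, left 12326 genes, or 75.3% of the table. Tests were two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. Groups were called non-overlapping where all 3 inosine libraries lay above or below all 3 control libraries.

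In total, 41 gene lists for pathways, sample quality and cell types were fixed before the data were examined, and 37 of them had at least 3 genes tested. The lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. For each list, members were also adjusted over the list alone. That adjustment does not correct for the number of lists, so some members can pass it by chance. Of the 577 different genes tested in any list, 23 stood in more than 1 list.

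Genes are named by a rule fixed at the same time as the lists. Its part 1 takes, among genes past the threshold with non-overlapping groups, a mean of at least 1 CPM and an ordinary gene symbol, the 10 largest rises and the 10 largest falls, filled up by the smallest unadjusted p where fewer pass. Part 2 takes from each list up to 4 members with the smallest p among those past the threshold, or the 1 member with the smallest p if none passes. Part 3 always takes Adar, Adarb1, Ada, Pnp, Hprt, Xdh and Gdf15. Any other gene named was chosen after its values were seen. Some genes that the rule takes are not reported here.

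The edgeR step was tested on simulated data drawn from the means and library sizes of the real libraries and edgeR's estimate of each gene's dispersion. In these data 200 single genes and a list of 21 further genes were changed. At 3 against 3 libraries it recovered 21% of 100 genes simulated at 1.5-fold and 72% of 100 genes simulated at 2-fold, with 10 calls among 12105 unchanged genes. DESeq2 1.42.0 recovered 42% and 85% of the same genes with 28 such calls, and limma-voom 20% and 73% with 9. In the simulated list test, the list of 21 genes, shifted by 0.5 on the log2 scale, was called and 0 of 30 unshifted lists were. Genes were drawn independently there, so the simulation cannot show how the preset correlation performs where genes vary together. Structure shared between libraries was not simulated either, so recovery in the real data may differ from these rates. In the real data the estimated correlation was 0.38 in the stress response list and 0.80 in the sinusoidal endothelium list.

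The alternatives planned at that time were other scalings, DESeq2, limma-voom, other low-count filters, a replicate block, other list tests and the omission of each library in turn. The reference annotation at hand is of GRCm38, so coordinates were taken from the deposited table alone, on GRCm39, counted from 1. The GRCm38 transcripts served only for GC content, matched by gene symbol. Terms from the table's own gene annotation were tested after the data were seen. RNA editing itself, which the title of the series concerns, was not analysed here, since counts per gene carry no edited bases. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the table and drew the plots.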

Results

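The series compared the liver transcriptome of mice given inosine by intraperitoneal injection with that of control mice, in 3 libraries per group. Its title places the comparison in work on liver A-to-I RNA editing and cancer cachexia, the wasting that accompanies tumours. The control libraries held 16891887, 16383896 and 17009895 counts and the inosine libraries 17505035, 16953667 and 16862048. Between 14687 and 14959 genes were detected per library. Albumin (Alb) was the most abundant mRNA in each library, with 6.68% to 9.16% of the counts.

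Crebrf fell in inosine-treated liver, from 36.5 ± 2.9 CPM in control to 14.6 ± 1.2 CPM (SD, n = 3), and it was the only gene past the threshold over all genes in edgeR. Its product is known as a negative regulator of the transcription factor CREB3. The log2 fold change was -1.32 (SE 0.10, edgeR adjusted p = 0.014), and all 3 inosine libraries lay below all 3 controls. Crebrf (gene ID 77128) lies on chromosome 17 of GRCm39, from 26918716 to 26995611 on the plus strand. No gene rose past the same threshold: edgeR called 0 higher and 1 lower of 12326 genes. At an unadjusted p under 0.05 there were 889 genes higher and 895 lower, where 616 in all would be expected by chance. DESeq2 called 215 genes, 111 higher and 104 lower, and the authors' deposited table holds 191 genes with a q-value under 0.05, 94 higher and 97 lower. Without inosine replicate 1, 2 or 3, or without control replicate 3, Crebrf did not pass edgeR (adjusted p = 0.063, 0.10, 0.055 and 0.054), and over all settings run its adjusted p ranged from 4.8e-16 with DESeq2 to 0.10. Over the 6 omissions of a library the log2 fold change of Crebrf lay between -1.26 and -1.39. Without control replicate 1, edgeR called 56 genes, 25 higher and 31 lower. They included the clock genes Dbp, Nr1d1, Cry1 and Per2 and the glucocorticoid-induced gene Fkbp5. On Dbp, Nr1d1 and Fkbp5 control 1 stood apart from the other controls, and the cause of the larger count was not tested. The genes called by DESeq2 numbered 496, 114, 130 and 127 without control replicates 1, 2 and 3 and inosine replicate 2.

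The other genes of smallest p did not pass and are given as values. On the higher side these were Cstf3, a subunit of the cleavage stimulation factor of mRNA 3' ends, at a log2 fold change of 0.79 (SE 0.09, edgeR adjusted p = 0.0502), and the clock gene Per2 at 0.61 (SE 0.07, edgeR adjusted p = 0.053). Kyat3, which encodes a kynurenine aminotransferase, measured 155 ± 18 CPM in control and 291 ± 36 CPM in inosine (SD, n = 3). Genes of the nucleolus stood among them, with Polr1b, a subunit of RNA polymerase I, at 0.63 and Nolc1, a nucleolar phosphoprotein, at 0.85. Pprc1, a coactivator related to PGC-1, was at 1.01, and Baz1a, Uspl1, Zfp110 and Ythdf1 lay between 0.47 and 0.73. On the lower side were Arsa, the lysosomal arylsulfatase A (-0.87), the sphingosine-1-phosphate transporter Spns2 (-0.98), Klhl24 (-0.62) and Cyp3a59 (-1.01), each at an edgeR adjusted p of 0.0502. Cyp3a59 belongs to a family of close paralogs among which reads can be shared, so its value is uncertain. Kank1 (-0.76), Cecr2 (-0.81), Dlc1 (-0.81), Tns3 (-0.56) and Atxn2 (-0.62) completed the 10. These genes were taken from those with non-overlapping groups, which numbered 2577 of the genes tested, 20.9%, where chance gives 10%.

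Genes of the unfolded protein response, which act when proteins accumulate unfolded in the endoplasmic reticulum (ER), were higher in inosine-treated liver. Of 21 tested members of the list for the unfolded protein and integrated stress response, 12 passed edgeR when adjusted over the list alone, 11 higher and 1 lower. Over all genes 0 passed edgeR, with the same count of 12 at an unadjusted p under 0.05, and DESeq2 called 8. Hspa5, the main ER chaperone (chromosome 2, 34662102 to 34666541), rose from 474 ± 43 to 956 ± 209 CPM (SD, n = 3) by that measure, at a log2 fold change of 1.01 (SE 0.16, adjusted p = 0.0024 over the list alone and 0.083 over all genes in edgeR). Creld2, an ER stress-inducible protein, rose by 1.66 (SE 0.28), the chaperone Hyou1 by 1.25 (SE 0.24), the co-chaperone Dnajb9 by 1.02 (SE 0.17) and the ER stress factor Manf by 0.95 (SE 0.17), again over the list alone. The other 6 members that rose over the list alone were Herpud1, which acts in ER-associated degradation, Pdia4, Hsp90b1 and the transcription factors Ddit3, Atf3 and Atf4, with Atf4 lowest at 0.24. Atf3 measured 1.73 ± 0.246 CPM in control and 3.46 ± 0.74 CPM in inosine (SD, n = 3). Trib3, a pseudokinase gene known as a target of Atf4 and Ddit3, fell over the list alone by 0.80 (SE 0.24). Apart from Hspa5, these members were chosen after their values were seen. The list's median log2 fold change was 0.34 (camera adjusted p = 6.1e-06). With an estimated correlation camera gave adjusted p = 0.91 (unadjusted p = 0.12). The authors' deposited table has 8 members higher and 0 lower at a q-value under 0.05. By library, the median of the list relative to the control mean was 0.11, 0.01 and -0.05 in controls 1 to 3 and 0.20, 0.41 and 0.62 in the inosine libraries. Control 1, the highest of the controls here, also stood apart on clock genes.

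**Figure D1:**
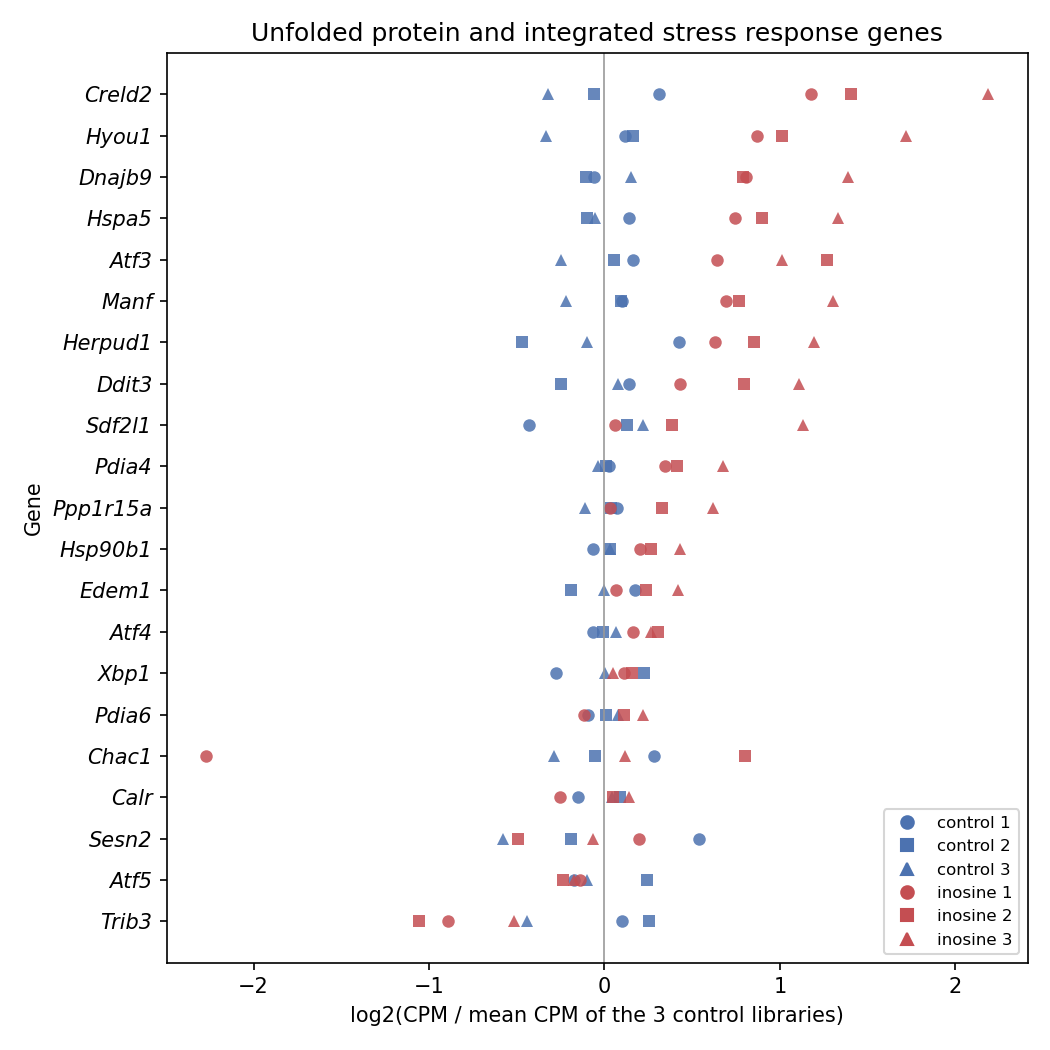
Each point is 1 library, placed by the log2 ratio of its TMM-scaled CPM to the mean of the 3 control libraries (x axis), for the 21 tested genes of the unfolded protein and integrated stress response list (y axis). Blue marks control and red inosine, with the shape giving the replicate. For Creld2, Hyou1, Dnajb9 and Hspa5 the 3 inosine libraries lie to the right of all 3 controls, and Trib3 lies to the left.

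In the heat shock and immediate early list, 14 of 19 genes were higher (median 0.20, camera adjusted p = 0.16), and without control replicate 1 the list was called. Hspa8, the constitutive HSP70, rose over the list alone from 1173 ± 123 to 1842 ± 306 CPM (SD, n = 3), a log2 fold change of 0.65 (SE 0.15, edgeR adjusted p = 0.047 over the list alone). Hsph1, chosen after its values were seen, also rose over the list alone, by 1.27 (SE 0.33). Among p53 targets the pro-apoptotic gene Bbc3 fell over the list alone by 1.25 (SE 0.33) while Aen, chosen after its values were seen, rose by 0.40 (SE 0.11). Neither passed over all genes (edgeR adjusted p = 0.185 and 0.196). The p53 list of 14 had a median of -0.01 and a test leaning upward (camera adjusted p = 0.92). The list of 20 NRF2 targets, genes of the response to oxidants, had a median of 0.00 (camera adjusted p = 0.66). Its member of smallest p, Gclc, measured -0.18 (SE 0.09, edgeR adjusted p = 0.40).

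Transcripts of red blood cells were lower in inosine-treated liver. All 6 tested erythroid genes fell when adjusted over the list alone in edgeR. Over all genes 0 passed edgeR, with 6 at an unadjusted p under 0.05, and DESeq2 called 4. Hba-a2, an alpha-globin gene (chromosome 11, 32246492 to 32247310), fell over the list alone from 157 ± 27 to 66.5 ± 15.2 CPM (SD, n = 3), a log2 fold change of -1.23 (SE 0.18, edgeR adjusted p = 9.1e-04 over the list alone). Hbb-bs measured -0.89 (SE 0.18) and Alas2, the erythroid enzyme of heme synthesis, -0.99 (SE 0.23). Hba-a1 (-0.73, with overlapping groups) and Hbb-bt (-0.85) are near-identical copies of Hba-a2 and Hbb-bs, and how reads were divided among them is uncertain. The named members other than Hba-a2 were chosen after their values were seen. The list's median was -0.94 (camera adjusted p = 3.7e-05). With an estimated correlation camera gave adjusted p = 0.91 (unadjusted p = 0.042). The authors' deposited table has 4 of the 6 lower at a q-value under 0.05.

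Markers of other cells that lie beside hepatocytes were lower as lists. The median was -0.37 over 14 genes of stellate cells and fibroblasts (camera adjusted p = 0.0027), -0.35 over 12 genes of the sinusoidal endothelium (0.0037) and -0.21 over 13 genes of Kupffer cells and macrophages (0.044). With an estimated correlation each of these 3 had adjusted p = 0.91. Not every inosine library lay below every control. For the Kupffer list the medians by library were -0.25, 0.19 and 0.06 in controls 1 to 3 and -0.13, -0.30 and -0.19 in inosine 1 to 3, so control 1 lay within the inosine range. For the stellate list they were -0.07, 0.17 and -0.11 in control and -0.53, 0.04 and -0.56 in inosine, and for the endothelial list -0.13, 0.06 and 0.06 in control and -0.73, -0.06 and -0.28 in inosine, so inosine 2 lay within the control range in both. In the endothelial list Fcgr2b, an Fc receptor, fell over the list alone by 0.49 (SE 0.13) and the phosphatase gene Ptprb, chosen after its values were seen, by 0.53 (SE 0.14). Neither passed over all genes (edgeR adjusted p = 0.178 and 0.191). No stellate or Kupffer gene passed over the list alone in edgeR, where 3 and 2 of them had an unadjusted p under 0.05; DESeq2 called 0 in either list. Acta2 measured -0.83 (SE 0.31, edgeR adjusted p = 0.30) and Adgre1 -0.41 (SE 0.15, edgeR adjusted p = 0.30). The Kupffer call was lost without control replicate 2 or 3 or inosine replicate 2 or 3 (camera adjusted p = 0.24, 0.26, 0.20 and 0.052), with a range of 4.8e-04 to 0.26 over the 6 omissions. The endothelial call was lost without inosine replicate 1 (0.15) and the stellate one without inosine replicate 3 (0.052). Medians of the lists not called were -0.42 for neutrophils (3 genes), -0.25 for T and NK cells (4), -0.48 for B cells (4), -0.16 for dendritic cells (6) and -0.13 for cholangiocytes (5). Their camera adjusted p ran from 0.25 to 1. The B cell list was called without inosine replicate 1. Csf3r, Cd3g, Cd22 and H2-Aa, the members of smallest p in the first 4 of these, measured -0.49, -0.97, -0.78 and -0.30. The cholangiocyte gene Spp1, osteopontin, rose over the list alone by 0.58 (SE 0.16) but did not pass over all genes (edgeR adjusted p = 0.201). Too few adipocyte (2), exocrine pancreas (1) and skeletal muscle (0) genes passed the filter for a test, with Fabp4 at -0.58 and Cela1 at -0.73. Zonation markers had medians of -0.08 for 12 periportal genes and 0.04 for 13 pericentral genes (camera adjusted p = 0.86 and 0.58), with Hal at -0.31 and Cyp2c37 at 0.66.

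In the acute phase list, 27 of 29 genes were higher, with a median of 0.18 (camera adjusted p = 7.2e-04), and adjusted p = 0.91 with an estimated correlation. No member passed over the list alone in edgeR, where 4 had an unadjusted p under 0.05, all higher. Orm3, an orosomucoid, had the smallest p, with 5.68 ± 1.53 CPM in control and 11.2 ± 3.6 CPM in inosine (SD, n = 3), and DESeq2 called it (adjusted p = 0.029). Of 32 genes for sensing double-stranded RNA and for the interferon response, 29 were lower, with a median of -0.22 (camera adjusted p = 0.011), and adjusted p = 0.91 with an estimated correlation. Again 0 passed over the list alone in edgeR, with 4 at an unadjusted p under 0.05 and 0 called by DESeq2. The list's call was lost without control replicate 2 or 3 or inosine replicate 3 (adjusted p = 0.20, 0.11 and 0.30), and ranged from 3.6e-05 to 0.30 over the 6 omissions. The median by library was -0.32, 0.18 and 0.11 in controls 1 to 3 and -0.14, -0.10 and -0.44 in the inosine libraries, so control 1 lay within the inosine range here too. The Kupffer and endothelial lists were lower in the same comparison. In the list of 14 inflammatory cytokines and NF-kB targets the median was -0.14 (camera adjusted p = 0.58), with Birc3 at -0.27.

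The editing and purine lists, which lie closest to the treatment and to the title, showed no difference that passed. A term of 11 purinergic receptor genes, tested after the data were seen, was called lower (camera adjusted p = 0.034, and 0.998 with an estimated correlation). It was among 38 terms called of 2192 tested, and 2 of its genes had an unadjusted edgeR p under 0.05, both lower. The wider term for ligand binding by G protein-coupled receptors (87 genes) was lower too (camera adjusted p = 0.034, and 0.998 with an estimated correlation). Adar, which encodes the main A-to-I editing enzyme of liver RNA, measured 26.4 ± 3.4 CPM in control and 25.7 ± 2.6 CPM in inosine (SD, n = 3), a log2 fold change of -0.04 (SE 0.12, edgeR adjusted p = 0.91). The sign turned without control replicate 3 or inosine replicate 3. Adarb1 measured -0.24 (SE 0.09, edgeR adjusted p = 0.31). The 6 editing enzymes had a median of -0.13 and 11 transcripts with known edited sites one of 0.01, with Tmem63b at 0.25 (camera adjusted p = 0.79 and 0.58). Among enzymes that handle inosine, adenosine deaminase (Ada) measured -0.38 (SE 0.28), purine nucleoside phosphorylase (Pnp) 0.05 (SE 0.19), the salvage enzyme gene Hprt 0.08 (SE 0.09) and xanthine dehydrogenase (Xdh) -0.37 (SE 0.15), with edgeR adjusted p of 0.55, 0.92, 0.71 and 0.33. The sign of Pnp turned without control replicate 2 or 3. Medians were -0.01 for 23 genes of purine salvage and breakdown, 0.09 for 8 of de novo purine synthesis and -0.15 for 5 adenosine receptors and nucleoside transporters (camera adjusted p = 0.996, 0.58 and 0.58). For the salvage list the test leaned upward against the negative median. The members of smallest p were Gmps (0.37), Prps2 (-0.31) and Adora1 (-0.38). Gdf15, a stress hormone linked to cachexia, was weakly expressed at 1.54 ± 0.52 and 1.31 ± 0.38 CPM (SD, n = 3; edgeR adjusted p = 0.80).

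Among metabolic lists, fatty acid oxidation and PPAR-alpha targets were higher, with 23 of 29 genes up and a median of 0.17 (camera adjusted p = 0.0064), and adjusted p = 0.91 with an estimated correlation. Cpt1a, the gatekeeper of mitochondrial fatty acid uptake, measured 421 ± 61 and 546 ± 69 CPM (SD, n = 3; log2 0.38, SE 0.14, edgeR adjusted p = 0.30). No member passed over the list alone in edgeR, with 3 at an unadjusted p under 0.05, and DESeq2 called 0. The list's call was lost without control replicate 2 or 3 or inosine replicate 1 (adjusted p = 0.12, 0.11 and 0.20), and its adjusted p ranged from 8.9e-06 to 0.20 over the 6 omissions. By library, the median of the list relative to the control mean was 0.23, -0.11 and -0.13 in controls 1 to 3 and 0.34, 0.16 and 0.03 in the inosine libraries, so control 1, which stood apart on clock genes, lay within the inosine range. Lipogenesis had a median of -0.03 over 18 genes, cholesterol synthesis -0.14 over 25 and gluconeogenesis 0.04 over 14. Of the lipogenesis genes 10 were lower and 8 higher. At an unadjusted edgeR p under 0.05 there were 5 lower and 1 higher, and 0 passed over the list alone. The 5 were Acss2 and, chosen after their values were seen, Srebf1 (-0.58), Acly (-0.54), Fasn (-0.435) and Acaca (-0.40). Pnpla3, chosen in the same way, was the higher one at 0.90. The median was -0.07 over 21 genes of glycolysis and glycogen, -0.14 over 26 of amino acid breakdown and the urea cycle, and 0.01 over 28 nuclear genes of oxidative phosphorylation. Bile acid genes (20) had a median of 0.01 and xenobiotic metabolism (28) one of -0.04, with a test leaning upward in the latter. None of these 8 was called, with camera adjusted p from 0.15 to 0.90, except that cholesterol synthesis passed without control replicate 2 and amino acid breakdown without control replicate 2 or inosine replicate 3. The members of smallest p in the lists other than cholesterol synthesis were Acss2 (-0.61), Ppargc1a (0.42), Gys2 (0.27), Hal (-0.31), Sdhd (0.23), Abcb4 (0.32) and Ugt1a1 (0.30), and none of these genes passed in edgeR.

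In the list of 23 genes for the growth hormone axis and secreted factors, Socs2, an inhibitor of growth hormone signalling, rose over the list alone from 8.35 ± 0.33 to 21.7 ± 8.4 CPM (SD, n = 3; log2 1.38, SE 0.26) and Igfbp2, chosen after its values were seen, by 0.72 (SE 0.17). Its median was 0.10 (camera adjusted p = 0.46), and fry for a change in either direction gave adjusted p = 0.016. Of 10 male-biased liver genes 9 were lower (median -0.49, camera adjusted p = 0.064). Cyp4a12a, the one of smallest p, had 37.8 CPM in control 1 and 3.06 and 1.46 CPM in the other controls. The inosine libraries had 0.1, 0.1 and 1.3 CPM, below every control. The size of its log2 fold change of -4.88 thus rests largely on 1 library, and levels in the others were low. How reads were divided between Cyp4a12a and its paralog Cyp4a12b is also uncertain. Top2a, a topoisomerase of dividing cells, fell over the list alone by 1.60 (SE 0.31) among 17 cell cycle genes, of which 14 were lower (median -0.56, camera adjusted p = 0.061). By library, the cell cycle median was 0.30, 0.28 and -0.57 in controls 1 to 3 and -0.33, -0.44 and -0.18 in inosine 1 to 3. Control 3 thus lay below every inosine library. The male-biased median was -0.30, 0.09 and 0.24 in control and -1.02, -0.77 and 0.22 in inosine, so inosine 3 lay within the control range. The cell cycle list was called without control replicate 3, inosine replicate 1 or inosine replicate 3, and the male-biased list without control replicate 1 or inosine replicate 3. Both lists were also called when the counts were scaled by library size alone and when trends over length and GC content were removed. In the list of 18 clock genes Per2 rose over the list alone, from 75.2 ± 3.2 to 114.8 ± 3.6 CPM (SD, n = 3; edgeR adjusted p = 7.3e-04 over the list alone). The clock list had a median of -0.12 and a test leaning upward (camera adjusted p = 0.83). Control 1 stood apart from controls 2 and 3 on other clock genes. The CPM of Arntl in control 1 was 9.0 times the mean of controls 2 and 3, which had 1.6 and 0.9 CPM, and the inosine libraries, with 1.6 to 3.1 CPM, lay near those 2 controls. Dbp measured 19.4 CPM in control 1 against 157.8 and 140.7 CPM, with the inosine libraries between them at 40.8 to 65.8 CPM. Fkbp5, a glucocorticoid-induced gene chosen like Arntl and Dbp after its values were seen, measured 196.7 CPM in control 1 against 25.5 and 31.4 CPM, and 97.8 to 197.1 CPM in the inosine libraries.

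**Figure D2:**
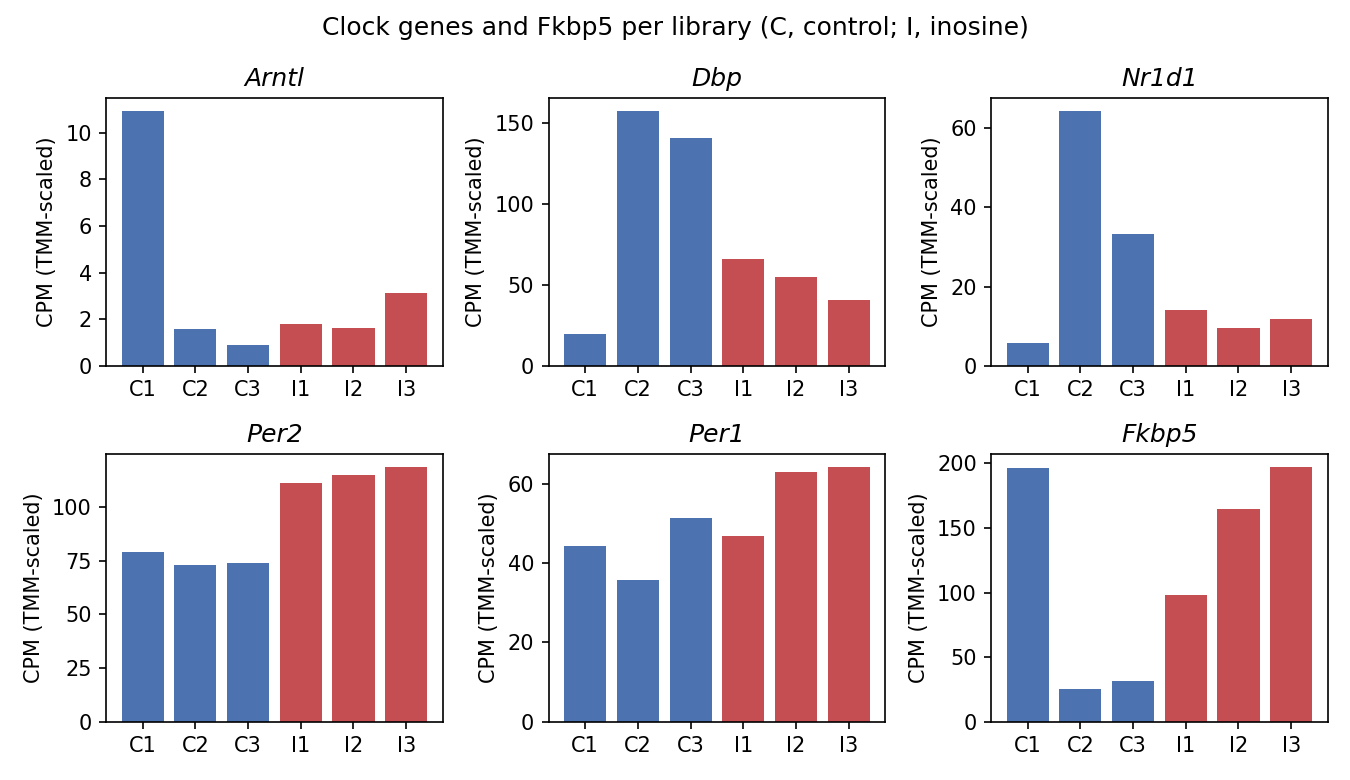
Bars give the TMM-scaled CPM (y axis) of 5 clock genes and the glucocorticoid-induced gene Fkbp5 in each library (x axis), with C1 to C3 for control and I1 to I3 for inosine. Control 1 differs from controls 2 and 3 on Arntl, Dbp, Nr1d1 and Fkbp5, whereas for Per2 the 3 inosine bars stand above all 3 control bars.

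Over all lists, camera called 8 of 37, 3 higher and 5 lower. With an estimated correlation 0 were called, with fry for one direction 0, and with fry for either direction 3, the stress response, the erythroid and the growth hormone lists. Regrouping the same 6 libraries into other sets of 3 and 3 gave up to 12 called lists with camera at its preset correlation. The 27 ribosomal protein genes, a check of sample quality, had a median of 0.02 (camera adjusted p = 0.45), with Rps27 at 0.16.

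**Figure D3:**
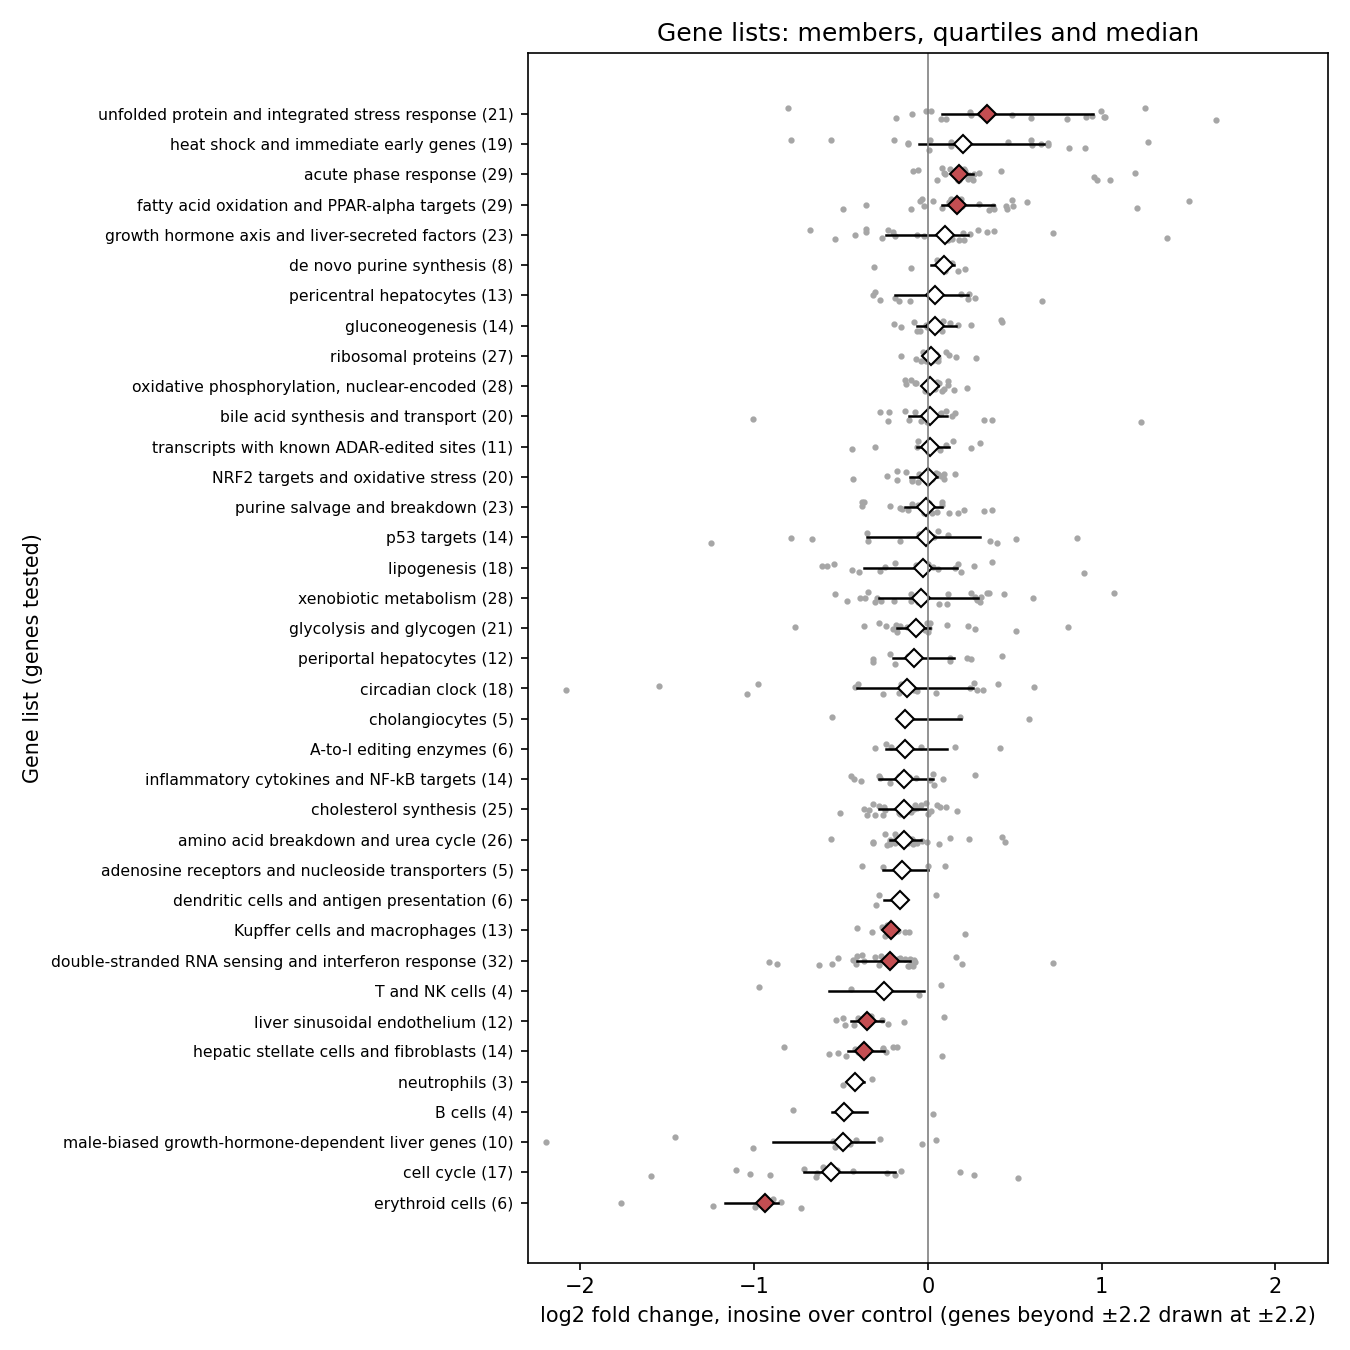
Grey points are single genes of each list (y axis, number tested in brackets) at their log2 fold change, inosine over control (x axis); black lines span the quartiles and diamonds mark the medians. Filled diamonds are the 8 lists with a camera adjusted p under 0.05, from the stress response list at 0.34 to the erythroid list at -0.94.

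The authors' deposited table and the edgeR fit differed in the number of genes past the threshold, not in direction. Of the 191 genes with a q-value under 0.05 in the authors' deposited table, 188 were tested here. All 188 had the same sign, an unadjusted edgeR p under 0.05 and non-overlapping groups. Both fits rest on the same libraries, so this match is not independent evidence. DESeq2 run on the rounded counts shared 187 genes with the authors' deposited table. The biological coefficient of variation in edgeR was 15.7%.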

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

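The robust and newer-deviance settings of edgeR, the threshold of 0.10, the list counts with DESeq2 size factors or without length and GC trends, DESeq2 without each library, and the counts adjusted over a list alone under other settings were chosen after the data were seen. The single gene called kept its count of 1 with DESeq2 size factors, library size alone or the stricter filter. DESeq2 called 215 genes (111 higher, 104 lower, 36 of at least 2-fold, 21 list members), and in the same order limma-voom 6 (1, 5, 2), no low-count filter 9 (1, 8, 2), robust shrinkage 17 (5, 12, 3, 1 list member), the newer deviance adjustment 6 (1, 5, 2) and the threshold of 0.10 101 (49, 52, 19, 8 list members); beyond the looser threshold itself, the cause was not tested. Leaving out 1 library gave 0 to 56 changed genes, 0 to 25 higher, 0 to 31 lower, 0 to 23 of at least 2-fold and 0 to 6 list members, each highest without control replicate 1; 35 of those 56 genes are among the 215 of DESeq2. The genes called by DESeq2 numbered 114 to 496, lowest without control replicate 2 and highest without control replicate 1, with 130 without control replicate 3 and 127 without inosine replicate 2. At an unadjusted edgeR p under 0.05 the omissions gave 1215 to 2417 genes. Lists called were 0 with an estimated correlation, 0 with fry in one direction, 3 with fry in either direction, 10 with library size alone (adding the cell cycle and male-biased lists), 8 with DESeq2 size factors, 11 without length and GC trends (adding those lists and ribosomal proteins), and 6 to 10 with 1 library left out. The stress response, erythroid and acute phase lists were called by camera in all 6 of those omissions. Adjusted over the list alone, 9 to 13 stress genes and 5 or 6 erythroid genes passed under every gene-level setting run. Adar turned to 0.06 and 0.04 without control replicate 3 and inosine replicate 3, within -0.13 to 0.06 over the omissions. Pnp turned to -0.07 and -0.06 without control replicates 2 and 3, within -0.07 to 0.32. Neither passed in any setting, and no other gene named by the rule changed sign. Of the genes named by the rule that had not passed, 28 passed with DESeq2, 14 with robust shrinkage, 12 without control replicate 1, 8 without a filter, 5 with limma-voom and 5 with the newer adjustment, each in the same direction. No pairing of the libraries by replicate number was seen in expression: same-numbered deviations correlated at -0.04, -0.03 and -0.02, within the range of -0.08 to 0.12 over all pairings, and not every library correlated best with its own number. This does not exclude that same-numbered animals were handled together. With the replicate block edgeR called 0 genes (0 lower, 0 of at least 2-fold, 1497 at an unadjusted p under 0.05), with Crebrf at adjusted p = 0.099 in a range of 4.8e-16 to 0.10 over all settings, and camera called 9 lists, 7 of them among the 8, without the Kupffer list (adjusted p = 0.062) and with the cell cycle and male-biased lists. The planned settings for tables without counts were not run, since counts were at hand. At this depth and number of libraries, simulated 1.5-fold changes were mostly missed by edgeR (21% recovered). The simulated libraries held no structure such as the place of control 1, so recovery in the real libraries may differ.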

Other observations

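The terms below, the tests of blood content, of one smaller share of non-hepatocyte cells, of collection time in the stress list and of length and GC in parts of the marker lists were chosen only after the result was seen; the split counts for DESeq2, the 2 lists and ribosome biogenesis were added after the first 3 split counts.

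Genes that build ribosomes were higher in inosine-treated liver as a group. Of 97 tested genes annotated to ribosome biogenesis, 33 were higher at an unadjusted edgeR p under 0.05 and 0 were lower. The median log2 fold change was 0.11 (camera adjusted p = 2.6e-07 over 2192 terms). With an estimated correlation camera gave adjusted p = 0.998, a value that other terms share (unadjusted p = 0.0515). Examples chosen after their values were seen were Tsr1, with 19.1 ± 2.0 CPM in control and 34.2 ± 6.0 CPM in inosine (SD, n = 3), Mphosph10 at a log2 fold change of 0.65 (SE 0.10) and the box C/D ribonucleoprotein genes Nop58 (0.79, SE 0.15) and Nop56 (0.63, SE 0.12). None of these passed edgeR over all genes, while DESeq2 called all 4. The 27 ribosomal protein genes had a median of 0.02, and the difference between the groups of genes was not tested. Protein processing in the ER was also higher (157 genes, 41 higher and 3 lower at an unadjusted p under 0.05, camera adjusted p = 1.9e-05). With an estimated correlation camera gave it adjusted p = 0.998 (unadjusted p = 0.147). Of 38 terms called, 33 were higher and 5 lower, and 0 were called with an estimated correlation. Called terms overlap, and some gave identical values, such as the Reactome terms of 74 genes for rRNA processing. The counts of terms are thus not counts of separate gene groups. The lower terms included that of 11 purinergic receptor genes, with a median of -0.38 (camera adjusted p = 0.034) and adjusted p = 0.998 with an estimated correlation. Of its genes, 2 were lower and 0 higher at an unadjusted edgeR p under 0.05.

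The first pattern is the stress list, higher in inosine. Removing each library's trend over transcript length and GC content left its median at 0.35 against 0.33 before, a ratio of 1.08 (camera adjusted p = 3.6e-05), which argues against such a bias as the cause. Collection time was weighed because control 1 stands apart on clock genes. In control 1 the median of the list lay 0.16 above the other 2 controls (interquartile range 0.34), where the inosine libraries lay 0.35 above them, so the value falls between what that explanation needs and what it forbids, and it cannot be told apart from the treatment here. A response to inosine may also account for the pattern, as a hypothesis that was not tested separately.

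The second pattern is the lower level of markers of non-hepatocyte cells, for which a response of the tissue to inosine stays open and untested. Less blood in the piece predicts lower markers of blood cells but not of cells resident in the tissue, and the highest median of the endothelial, stellate and Kupffer lists was -0.21, but the groups overlapped by library in each of these lists, so it stays open for the whole pattern. For the erythroid part it stays open too: the medians of the neutrophil, T and NK cell and B cell lists were -0.42, -0.25 and -0.48, and the highest of them, -0.25, lay between the bounds set for and against it. One smaller share of all such cells predicts an equal fall and is not excluded, since the erythroid median minus that of the other lists was 0.16, 0.07 and -0.31 in controls 1 to 3 and -0.21, -0.85 and -1.11 in inosine 1 to 3, where the highest inosine value lay 0.11 above the lowest control. The length and GC test was set before its result for all 4 lists and stayed undecided, with a smallest ratio of corrected to uncorrected median of 0.75; split afterwards, it argues against that bias for the erythroid, endothelial and stellate lists (0.95) and leaves the Kupffer list undecided (0.75).

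The third pattern is the place of control 1. The first principal component (32.5% of the variance) put it at -6.3, on the side of the inosine libraries (-12 to -17.2) and away from controls 2 and 3 (31.7 and 18.4), while the second (23.5%) set it apart from all others, at -33.8 against 1.3 to 13.5. Over all genes, the difference of inosine from one control correlated with that of control 1 from the other, at 0.23 and 0.33 across genes in the 2 pairings that share no library; genes are not independent replicates. A shift in collection time shared in part by control 1 and the inosine libraries may contribute to the differences between groups, though any other shared state would give the same correlations, and batch and collection time are not given in the sources used here. Single genes, chosen after their values were seen, went both ways: Nr1d1 (5.6 CPM in control 1, 64.4 and 33.2 CPM in controls 2 and 3, 9.5 to 14.0 CPM in inosine) and Fkbp5 placed the inosine libraries nearer to control 1, whereas Arntl placed them near controls 2 and 3, and Per2 in control 1 (78.9 CPM) lay near the other controls (73.1 and 73.7 CPM).

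The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05, so the counts are given as values. Changed genes numbered 1, with 5 as the highest of the other splits and 3 splits at least as high as the real one, itself included. Lists called by camera numbered 8, with a highest other value of 12 and 6 splits at least as high. The real split was the highest (1 of 10) for genes at an unadjusted p under 0.05 (1784, next 1066), genes called by DESeq2 (215, next 60), stress genes over the list alone (12, next 0), erythroid genes over the list alone (6, next 0) and ribosome biogenesis genes at an unadjusted p under 0.05 (33, next 3). The stress, erythroid and ribosome biogenesis genes were singled out because they stood out under the real split. Its first place for these groups of genes was therefore largely fixed in advance and is no support. The next-highest values of 1066 and 1048 came from splits that set control 1 and a pair of inosine libraries against the rest, which points to a structure among the libraries.

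Cyp4a12b was counted at 226 CPM in control 1 and at 0 in the other 5 libraries, which by counting error alone allows up to 0.183 CPM there. How reads were divided between it and its paralog Cyp4a12a is uncertain, and that bound does not cover it. The authors' deposited table lists Cyp4a12b at a log2 fold change of -26.62 with a q-value of 3.9e-08, a call that rests on 1 library.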
